A study of Mus musculus with 4 samples.

How the data were processed

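Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the transcription factors Slug (gene Snai2) and Snail (gene Snai1) sit on the genome of mouse breast cancer cells. The 4 samples were 2 ChIP libraries and 2 input DNA libraries. pBl.1G is an epithelial line with high Slug and pBl.3G a mesenchymal line with high Snail, per the labels. Both came from tumours of MMTV-PyMT mice, in which a viral promoter drives the polyoma middle T oncogene in the mammary gland. Cells were fixed in 1% formaldehyde for 10 min and the DNA sonicated to fragments of about 200 to 500 bp, per the labels' protocols. The Slug library was made with a rabbit monoclonal antibody to Slug. The antibody of the Snail library is labelled as directed at Snail and Slug together.

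The 2 deposited files used here are peak lists, 1 for each ChIP library. Bowtie, MACS 1.4.2 and the mouse build mm10 are named in the submitters' processing notes, and each peak name in the files begins with the name of that peak caller. The version of Bowtie, the MACS settings and whether the input of the same cells served as control are not given in the sources used here. Each deposited row holds a position and a score given by the authors' peak caller. By the convention of MACS 1.4 this score is a log-transformed p-value of the peak, but the files do not state the scale. The lowest score was 50 in both lists, and 23 Slug and 39 Snail peaks scored 3100 or more, where values pile up. The score was used to rank or filter peaks within its own list. It depends on the depth of the library and of its control. Slug and Snail scores printed side by side therefore do not compare strength. An alternative applied the same cut of 100 to both lists, keeping 39.7% of Slug and 63.0% of Snail peaks. That cut may not be equally strict in the 2 lists. No read counts or signal tracks were used here, so sequencing depth is unknown and no peak has an estimate of its height. The 2 input libraries had no peak list of their own and were not used here.

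All calculations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. Peak starts were converted from 0-based to 1-based positions. Genes came from a table of the RefSeq annotation of GRCm38.p6, the assembly that mm10 shares. It gave the chromosome, start and end of 49943 genes on chromosomes 1 to 19, X and Y, of which 21887 were protein-coding. The table held no strand, exons or sequence. Transcription start sites were therefore not used. In their place a peak was measured to the nearer of the 2 ends of a gene, 1 of which is the start site. This departs from the design fixed before the data were examined, which measured from start sites. For the same reason the planned CAGGTG E-box and other motif counts, the filter on repeats, the classes for exons and untranslated regions, and the matching on promoter CpG content were not run, and the planned window of the gene body plus its upstream stretch took 10 kb on each side.

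Peaks of the 2 lists were called shared when they overlapped by at least 1 bp. Observed overlaps were set beside 100 seeded placements, in which the other list's peaks kept their widths and chromosomes and were placed evenly between the first and last annotated gene or peak. The planned avoidance of assembly gaps was not applied. Placed peaks could thus fall into gaps, which may lower the random overlap and raise the ratios to it. A further 100 placements, added after seeing the data, moved each peak to a random gene end while keeping its distance to its own nearest end. Peak midpoints were classed as within 1 kb of a gene end, elsewhere in a gene body, or intergenic. A protein-coding gene was said to have a peak when a midpoint lay within 10 kb of either end.

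Fixed before the data were examined were 20 gene lists with 448 memberships, 5 of them controls, and every symbol was found in the gene table directly or by a synonym. Each list's share of genes with a peak was given a percentile among 10000 random lists of protein-coding genes of the same size, matched member by member on gene length quintile. A list was called above or below the random range at percentiles of at least 97.5 or at most 2.5, so chance alone puts about 2.5% of lists on each side. The percentiles describe these libraries and are not p-values across replicates. Neighbouring members can share 1 peak, which the random lists do not imitate. The named genes were chosen by a rule fixed in advance: 18 genes of epithelial-mesenchymal transition (EMT) and mammary biology whatever they showed, the 2 members of each non-control list with the highest-scoring Slug peak and the 2 with the highest-scoring Snail peak, and the 5 genes with the highest-scoring peak within 1 kb of an end among Slug peaks without overlap, Snail peaks without overlap and shared Slug peaks. Further members are named where they make up a stated category of a list, and were then chosen after their values were seen. The single-gene result of 1 list member is not reported here.

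Each factor was mapped in 1 library, so no test across libraries was possible and no p-value is given. Shares carry 95% Wilson intervals and differences of shares Newcombe's interval built from them. Differences of medians carry 95% intervals from 1000 bootstrap draws of peaks. All of these cover counting error only and not the spread between cultures or ChIP experiments. The functions were tested on simulated data: of placed peaks with a planted overlap of 30.9%, 31.0% were found to overlap, and 200 random lists of 25 genes without effect gave a median percentile of 50.2 against the real Slug calls. Alternatives were a score of at least 100, equal numbers of peaks, stricter definitions of overlap, other gene windows and other matching of the random lists.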

Results

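The study asked how Slug and Snail differ in their ability to switch on the EMT program in breast cancer cells. It mapped Slug in epithelial pBl.1G cells and Snail in mesenchymal pBl.3G cells. The Slug list held 41612 peaks that covered 9.51 Mb, with a median width of 206 bp (quartiles 163 and 257 bp). The Snail list held 28375 peaks that covered 25.6 Mb, with a median width of 722 bp (quartiles 476 and 1124 bp). The Slug list was thus 1.47 times longer while the median Snail peak was 3.50 times wider. Within their own lists, the median score was 81.1 for Slug (quartiles 59.1 and 149) and 151 for Snail (quartiles 76.1 and 559). Factor, antibody and cell line all differed between the libraries, with 1 library of each, so every comparison below is between these 2 libraries. Positions are on mm10. Genes are given by their RefSeq span, and the strand was not used.

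The first comparison concerned where the peaks lay relative to genes. Snail peaks gathered at gene ends and Slug peaks mostly did not. Of the Snail peaks, 43.4% (95% interval 42.8 to 44.0) had their midpoint within 1 kb of a gene end, against 6.44% for the same peaks placed at random. Of the Slug peaks, 9.96% (9.67 to 10.3) did so, against 6.30% at random. Another 49.1% of Slug peaks lay elsewhere in gene bodies and 41.0% between genes, whereas 34.4% and 22.2% of Snail peaks did. The intervals of the 2 lists do not touch in any class.

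**Figure D1:**
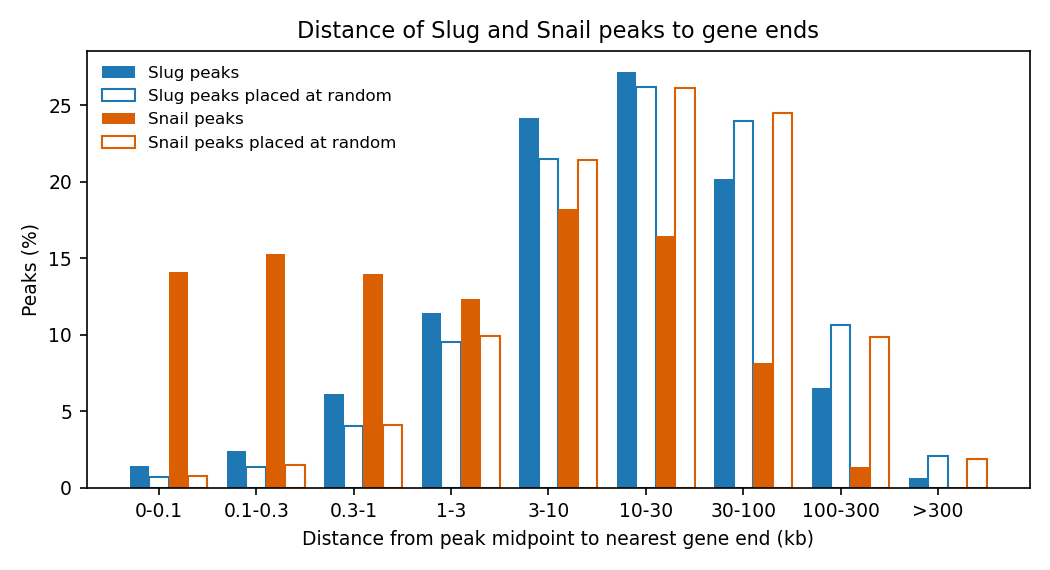
Share of peaks (vertical axis, percent) by distance from the peak midpoint to the nearest gene end (horizontal axis, kb) for the Slug list (blue) and the Snail list (orange), with open bars for 1 random placement of the same peaks. Within 0.1 kb of a gene end lay 14.1% of Snail peaks and 1.46% of Slug peaks, and between 10 and 30 kb 16.4% and 27.2%.

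Named sites at gene ends were taken from the top of each list by score. The 5 genes with the highest-scoring unshared Snail peaks within 1 kb of an end were Urgcp, Wdr45b, the histone H4 gene H4c14, and the adjoining pair Gak (cyclin G-associated kinase) and Tmem175, whose ends share 1 peak at chromosome 5, 108629176 to 108630172, with a score of 2676. The Urgcp peak spanned chromosome 11, 5761546 to 5762807 and scored 2869. Among Slug peaks without a Snail partner they were Susd4, the protocadherin gene Pcdhb22, the ketone body enzyme genes Oxct2a and Oxct2b, and Tiam2, an exchange factor for Rac. The Susd4 peak spanned chromosome 1, 182763631 to 182763986 and scored 1239. These peaks lacked an overlap, but several of the genes had peaks of both factors. Tiam2 had a Snail peak with a score of 776 within 1 kb of the same end. Oxct2b had a Snail peak within 10 kb, with a score of 141. Urgcp, Wdr45b and H4c14 had Slug peaks within 10 kb, with scores of 152, 90.6 and 121. Susd4, Pcdhb22, Oxct2a, Gak and Tmem175 had no peak of the other factor there. Among shared Slug peaks the 5 genes were Shq1, Lars2 (mitochondrial leucyl-tRNA synthetase), Asmt, Oasl1 and Scai, with Slug scores between 1159 for Scai and 2498 for Shq1. All but the Scai peak were among the 100 highest-scoring Slug peaks, whose lowest score was 1504. As described in the last part, peaks that strong may mark regions that collect reads in any library, which could not be told from binding.

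Gene ends accounted for most of the high-scoring Snail peaks. In the top quintile of Snail peaks by score 85.9% (85.0 to 86.8) lay at a gene end, against 17.1% (16.2 to 18.1) in the lowest. In the Slug list the shares were 9.13% (8.53 to 9.77) and 9.61%, and their 95% intervals overlap. Raising the lowest accepted score to 100 took the Snail share to 58.4% and left the Slug share at 9.78%.

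**Figure D2:**
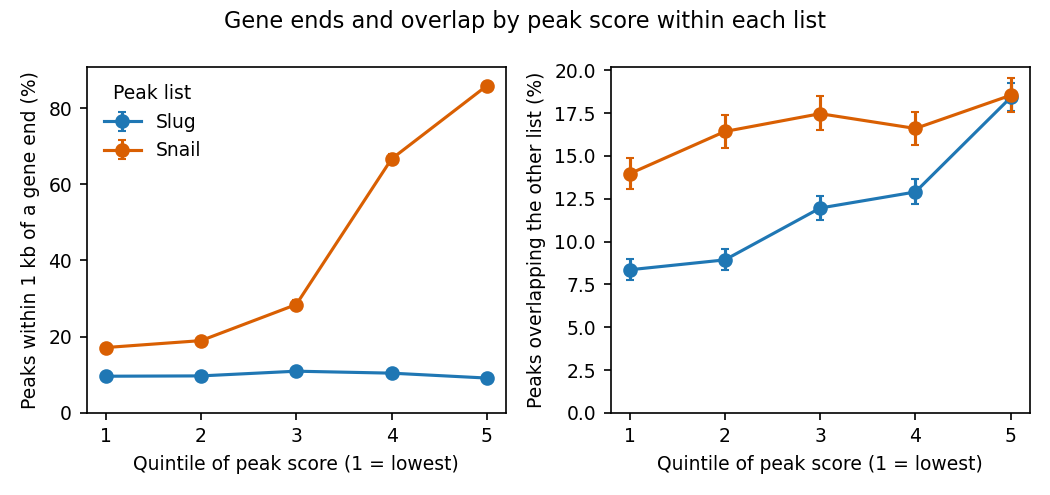
Share of peaks within 1 kb of a gene end (left, percent) and share overlapping a peak of the other list (right, percent) by quintile of peak score within each list, for Slug (blue) and Snail (orange). Points are shares and bars 95% Wilson intervals; the Snail gene-end share goes from 17.1% in the lowest quintile to 85.9% in the highest, while the Slug share stays between 9.13% and 10.9%.

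The second comparison asked how far the mapped sites coincide. Most did not: 12.1% of Slug peaks (5038 peaks, 11.8 to 12.4) overlapped a Snail peak, and 16.6% of Snail peaks (4709 peaks, 16.2 to 17.0) overlapped a Slug peak. Random placement gave 1.28% (at most 1.44% in 100 placements) and 1.87% (at most 2.07%), so the observed overlaps were 9.48 and 8.86 times higher. When the placed peaks kept their distances to gene ends, the ratios were 6.71 for Slug and 3.44 for Snail peaks. These placements drew the ends of all annotated genes alike and so kept no preference for certain kinds of gene. Snail peaks, however, lay within 1 kb of 48.7% of protein-coding genes and 4.18% of pseudogenes. Shared sites included the peak at the end of Snai1 itself, the peak next to the simple-epithelium keratin gene Krt8 (Slug at chromosome 15, 102005197 to 102005898, score 870), and a site inside Cdh1. A shared site inside Zeb2, at 45045518 to 45045912 of chromosome 2, scored 864 in the Slug list and 88.5 in the Snail list. Of shared Slug peaks 33.5% (32.2 to 34.8) lay at a gene end, against 6.72% (6.47 to 6.98) of the others. The reverse held in the Snail list, with 34.0% (32.7 to 35.4) of shared and 45.3% (44.7 to 45.9) of other peaks at a gene end. Shared peaks of both lists mark the same places, so their 2 shares had to be nearly alike. The opposite directions follow from the gene-end shares of the whole lists, 9.96% for Slug and 43.4% for Snail. A reciprocal overlap of 50% left 3.73% of Slug and 5.47% of Snail peaks shared.

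Within each list, shared peaks scored slightly higher by the median. The medians were 103 against 79.0 in the Slug list, a difference of 24.2 (20.9 to 27.2), and 168 against 148 in the Snail list, a difference of 20.3 (9.98 to 33.3). Neither direction held under every definition. Averaged over quintiles of peak width the Slug difference was -10.4, and with reciprocal overlap the Snail difference was -71.1.

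The third comparison placed both lists on genes. The scores given for members of a list, and the highest among them, are of peaks within 10 kb of a gene end unless a peak is said to lie deeper inside the gene. Of 21887 protein-coding genes, 10422 (47.6%) had a Slug peak and 14020 (64.1%) a Snail peak within 10 kb of an end. Both factors had a peak near 8051 genes, Slug alone near 2371, Snail alone near 5969 and neither near 5496. Independent calls would have put both near 6676 genes, so the observed number was 1.21 times higher. Within 1 kb of an end, 2657 genes had a Slug peak and 10662 a Snail peak, and 1943 had both, against 1294 for independent calls. At the genes of the factors themselves, Snai1 (chromosome 2, 167538195 to 167542814) had 2 Slug peaks and 4 Snail peaks within 10 kb. The Snail peak at 167537771 to 167538551, score 944, overlapped both Slug peaks, which scored 118 and 51.1. Snai2 (chromosome 16, 14705852 to 14709395) had 1 Snail peak across its low-coordinate end, at 14705158 to 14706152 with a score of 783, and no Slug peak within 10 kb.

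Epithelial junction genes and epithelial factors lay near Slug peaks more often than random genes of like length, while the epithelial polarity list (percentile 89.3) and the luminal markers (91.0) were inside the random range. Of 26 epithelial junction genes 23 (88.5%, 71.0 to 96.0) had a Slug peak within 10 kb, against a median of 53.8% in random lists (percentile 99.98). Of 18 epithelial transcription and splicing factors 16 (88.9%, 67.2 to 96.9) did (percentile 99.92). The Snail list reached 22 of the 26 junction genes (percentile 96.9) and 13 of the 18 factors (72.2%, the median of random lists). For the factor list the difference between the 2 libraries was itself at the low edge, at percentile 0.635 of the same difference in random lists. The neuronal and hepatocyte control lists were as low, at 0.565 and 0.68. Of the junction list it was at percentile 4.24, inside the random range, and within 1 kb at 1.20, below it. With gene bodies counted, the Snail share of the junction list was above the range too (92.3%), as it was without matching (percentile 98.8). With 1 kb windows the Slug share of the junction list was 26.9% at percentile 97.4, just under the limit for a call. With a score of at least 100 it was 46.2% at percentile 97.7.

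Single epithelial genes show how the sites were arranged. Cdh1, which encodes E-cadherin, the main adhesion protein of epithelial junctions (chromosome 8, 106603350 to 106670247), had 3 Slug peaks inside the gene and 1 at 106674299 to 106674563, 4.18 kb beyond its high-coordinate end, with the highest score of the 4, 240. Its single Snail peak, at 106618700 to 106620999 with a score of 322, lay inside the gene and overlapped the Slug peak at 106620907 to 106621186. Epcam, another epithelial adhesion gene, had Slug peaks with scores of 351 and 263 and 1 Snail peak with a score of 50.7, close to the lowest accepted. Cldn4, a tight junction claudin, had 4 Slug and 2 Snail peaks within 10 kb, and Nectin4 had 3 Slug peaks, the highest at 332, and 1 Snail peak at 292. Among the factors, Grhl2, Grhl3, Ovol2 and Ehf had a Slug peak and no Snail peak within 10 kb. The highest Slug scores of Grhl2 and Ehf there, 66.7 and 61.9, were below the Slug median of 81.1, and that of Ovol2 was 155. The Grhl3 peak, at chromosome 4, 135573413 to 135573892, lay at the gene's high-coordinate end with a score of 404. Esrp1, an epithelial splicing regulator, was the only member with the opposite pattern, with a Snail peak 9.50 kb outside the gene at a score of 1777 and no Slug peak. Rbm47 had 1 peak of each factor within 10 kb, with scores of 502 for Slug and 448 for Snail. Among the junction genes Tjp1, Cdh1 and Dsg2 had only Slug, and Pkp3 and Ctnna1 only Snail peaks within 10 kb.

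**Figure D3:**
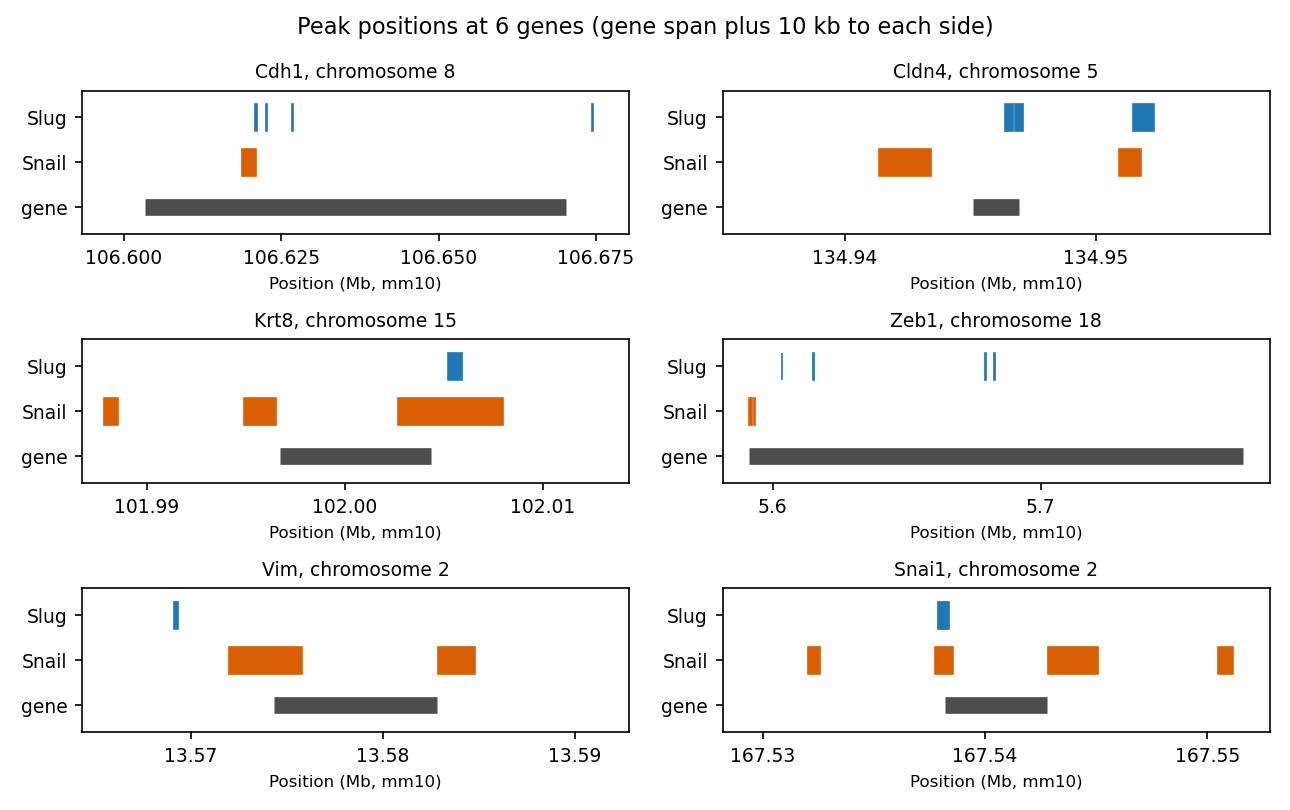
Positions of Slug peaks (blue), Snail peaks (orange) and the gene span (grey) at 6 genes, each with 10 kb to either side (horizontal axis, Mb on mm10); bar height carries no value. At Cdh1 and Zeb1 the 3 and 4 Slug peaks inside the gene lie away from its ends, and at Zeb1, Vim and Snai1 a Snail peak covers the low-coordinate end.

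Epithelial polarity genes were near Snail peaks in 15 of 16 cases (93.8%, 71.7 to 98.9, percentile 98.8) and near Slug peaks in 11 (68.8%, 44.4 to 85.8, percentile 89.3). Within 1 kb of an end, 10 genes had a Slug peak (percentile 100) and 9 a Snail peak (percentile 57.9). With gene bodies counted, all 16 had a Slug peak (percentile 99.94) and the Snail call ended, at percentile 97.2. The difference between the libraries was at percentile 71.0 within 10 kb and at 0.035 within 1 kb, where the neuronal (0.02), endothelial (0.16), immune cell (0.21) and hepatocyte (1.16) controls were also below the random range. Llgl2, a polarity gene of the lethal giant larvae family, had 5 Slug peaks within 10 kb, the highest at 246, and 2 Snail peaks, the highest at 652. Pard3 had 22 Slug and 4 Snail peaks within its span of 549 kb and its flanks. Ezr, which encodes ezrin, had the highest Snail score of this list, 1613.

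Transcription factors that drive EMT were frequent among genes near Snail peaks: 17 of 19 (89.5%, 68.6 to 97.1) against 57.9% in random lists (percentile 99.89). Slug peaks lay near 12 (63.2%, 41.0 to 80.9, percentile 94.6), and the difference between the libraries was inside the random range in every setting tried (percentiles 44.8 to 89.5 in the alternatives). Slug shares of this list were above it within 1 kb (7 genes, 36.8%, percentile 99.71) and with gene bodies counted (78.9%, percentile 98.98). The high Snail share was not particular to EMT factors. Of the 164 housekeeping genes described in the last part, 158 (96.3%) had a Snail peak within 10 kb, against 64.6% in random lists (percentile 100). Among the EMT factors with a Snail and no Slug peak within 10 kb were Zeb1, Twist1, Prrx1, Foxf2 and Snai2, and Gsc alone had the reverse. The Snail peak of Zeb1 (chromosome 18, 5591327 to 5775468) covered its low-coordinate end with a score of 581, whereas its 4 Slug peaks were at least 12.2 kb inside, with scores from 86.4 to 176. Twist1 had Snail scores of 663 and 193. Zeb2 had 3 Snail peaks near its ends, the highest at 721, and 1 Slug peak at 60.4, with higher Slug scores of 524 and 864 deeper in the gene. Tcf4 had the highest Snail score of this list, 1822, and Foxc2 the next, 1471. Within 10 kb of an end, Snai3 and Sox4 had the highest Slug scores, 309 and 167.

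Mesenchymal genes did not stand apart in either list. Slug peaks lay near 14 of 30 (46.7%, 30.2 to 63.9, percentile 27.5) and Snail peaks near 21 (70.0%, 52.1 to 83.3, percentile 51.2). Vim, which encodes the intermediate filament vimentin, had a Snail peak of 3839 bp over its low-coordinate end with a score of 921, a second with a score of 646, and 1 Slug peak at 66.1. Cdh2 (N-cadherin) had a Snail peak with a score of 990 at its high-coordinate end and only internal Slug peaks. Fn1 (fibronectin) had a Snail peak with a score of 1159 over its high-coordinate end and another with a score of 217 centred 2.03 kb beyond its low-coordinate end, with a Slug peak of score 76.9 inside the latter. A further Slug peak of Fn1, 23.8 kb inside the gene at 71609083 to 71609389 of chromosome 1, scored 567. Mmp14 and Mmp2, which encode matrix metalloproteinases, had the highest Slug scores of this list within 10 kb of an end, 503 and 355. Nt5e and Itgav had the highest Snail scores, 1477 and 1225. Collagen and matrix genes gave 15 of 22 for Slug (percentile 89.6) and 16 for Snail (percentile 59.3), with Col1a1 at a Snail score of 1568 and a Slug score of 243. No gene of that list had a Slug peak within 1 kb of an end, which was at percentile 2.27.

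**Figure D4:**
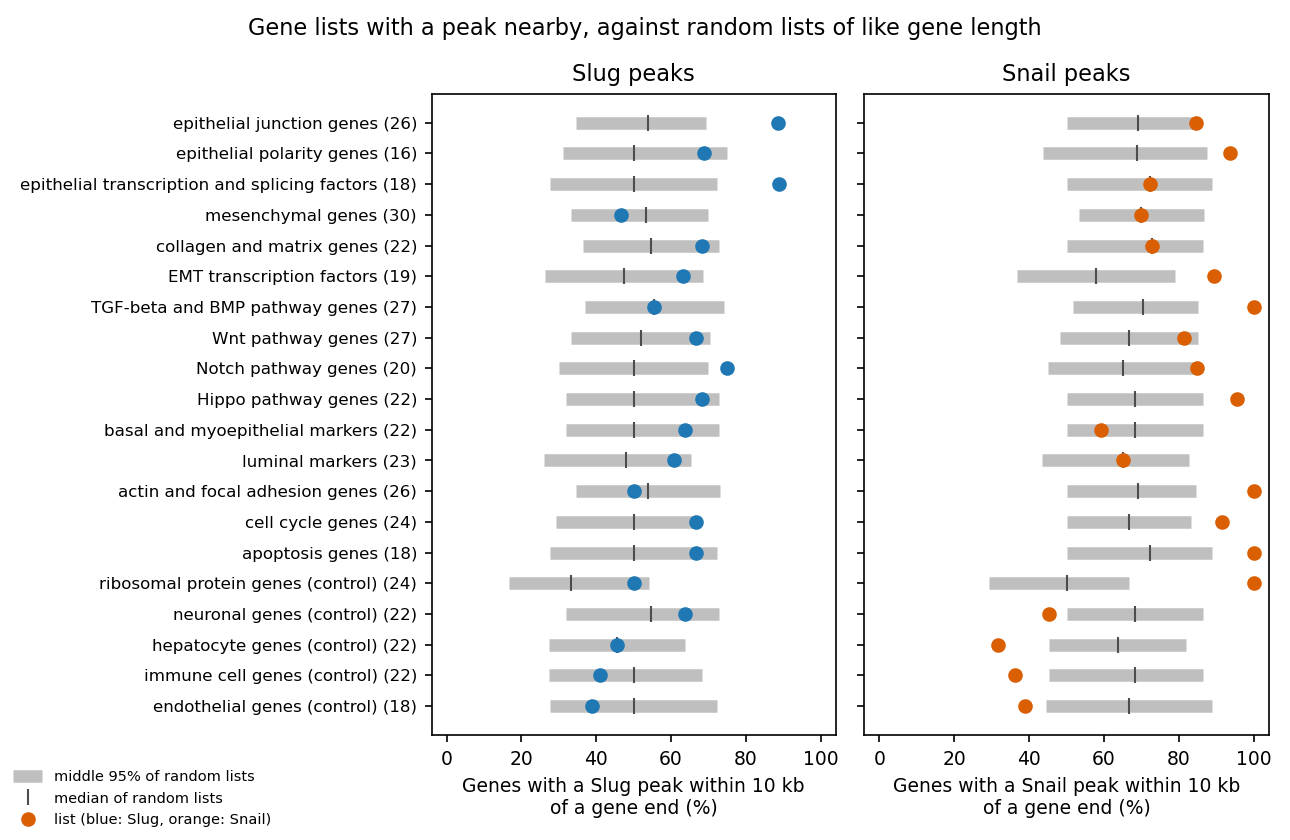
Share of the genes of each fixed list (number of members in brackets) with a Slug peak (left) or a Snail peak (right) within 10 kb of a gene end (horizontal axis, percent), as coloured points, with the median (tick) and middle 95% (grey bar) of 10000 random lists of like gene length. For Slug the junction genes (88.5%), the epithelial factors (88.9%) and the Notch genes lie to the right of the bar; for Snail 7 study lists and the ribosomal protein genes do.

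Several signalling lists and the cytoskeletal list lay near Snail peaks more often than random lists. All 27 TGF-beta and BMP pathway genes had one (87.5 to 100%, against 70.4% in random lists), and 15 had a Slug peak (55.6%, percentile 54.6). The difference was at percentile 99.4, falling to 93.1 for peaks with a score of at least 100, and that of the ribosomal protein control was at 99.89, above the range in all 6 alternatives. Smad4, the common mediator of the pathway, carried the highest Snail score of the list, 1946, at its high-coordinate end, and Slug scores of 308 and 152. Bmp7 carried the highest Slug score, 1167, at chromosome 2, 172868929 to 172869443. Tgfb2 had 2 Slug peaks within 10 kb, the highest at 227, and 1 Snail peak at 66.5. All 26 actin and focal adhesion genes had a Snail peak (percentile 100) and 13 a Slug peak (percentile 39.2), a difference at percentile 99.7 that fell to 90.3 when gene bodies were counted. Pxn, which encodes the adhesion scaffold paxillin, had a Snail peak with a score of 3100, and Vcl (vinculin) one of 1980. Hippo pathway genes had Snail peaks in 21 of 22 cases (percentile 99.88), among them Ccn2 with a score of 1329 and Yap1 with 1036, and Slug peaks in 15 (percentile 93.8). All 18 apoptosis genes had a Snail peak (percentile 99.92) and 12 a Slug peak (percentile 89.3), with Mcl1 at a Snail score of 1572 and Bak1 at a Slug score of 321. Cell cycle genes had Snail peaks in 22 of 24 cases (percentile 99.8) and Slug peaks in 16 (percentile 96.5, or 97.7 with matching on gene density), among them Pcna with a Snail score of 1898 and Ccnd3 with a Slug score of 962. For the Hippo, apoptosis and cell cycle lists the difference between the libraries was inside the random range, at percentiles of 81.9, 83.4 and 68.2, but within 1 kb it was above it for the Hippo list (99.97) and the cell cycle list (99.89), and for the latter also with a score of at least 100 (99.8) and with equal numbers of peaks (97.8). The Slug share was above the range for the Hippo list with equal numbers of peaks (percentile 98.8) and for the apoptosis list within 1 kb (98.7).

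These Snail shares stood beside an equally high share in a control. All 24 ribosomal protein genes, which every cell uses, had a Snail peak (percentile 100), and 12 had a Slug peak (percentile 93.1). Control genes of other tissues had Snail peaks less often than random lists: 10 of 22 neuronal genes (percentile 1.66), 7 of 22 hepatocyte genes (percentile 0.1), 8 of 22 immune cell genes (percentile 0.165) and 7 of 18 endothelial genes (percentile 0.675). With gene bodies counted, the neuronal and endothelial calls ended, at percentiles of 5.39 and 7.36, and the neuronal call also ended without matching on gene length (4.08). The same lists had Slug peaks at 14, 10, 9 and 7 genes, at percentiles of 85.0, 50.2, 26.2 and 16.7.

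Notch pathway genes had Slug peaks in 15 of 20 cases (percentile 99.3), a call lost with a score of at least 100 (percentile 49.1), with equal numbers of peaks (74.1) and within 1 kb (40.3), and Snail peaks in 17 (percentile 97.0). Notch3 and Hey1 had Slug scores of 669 and 632, and Jag1 a Snail score of 1174. Wnt pathway genes had Slug peaks in 18 of 27 cases (percentile 94.2) and Snail peaks in 22 (percentile 95.1). The Snail share was above the random range with gene bodies counted (99.6) and with matching on gene density (98.0), and the Slug share without matching (97.7). Apc, the tumour suppressor of this pathway, had a Snail score of 1755 and Wnt7b a Slug score of 534. Axin2 had 1 Slug and 2 Snail peaks, none above 94.0. Lgr5, a stem cell marker, had no peak within 10 kb of an end but 5 Slug peaks inside it. Basal and myoepithelial markers had Slug peaks in 14 of 22 cases (percentile 85.8) and Snail peaks in 13 (percentile 14.6, or 1.62 with a score of at least 100). The difference was at percentile 4.58 and fell below the random range with a score of at least 100 (0.865), within 1 kb (0.605) and with gene bodies counted (0.49), where the Slug share was at percentile 99.8. Within 1 kb the neuronal (0.02), endothelial (0.16), immune cell (0.21) and hepatocyte (1.16) controls were below the range too. The basal keratin gene Krt5 had 3 Slug peaks, the highest at 120, and no Snail peak within 10 kb, and Krt14, Krt17, Oxtr and Jag2 likewise had only Slug peaks. Their highest scores were 187, 76.1, 183 and 50.6, the last close to the lowest accepted. Mylk had the highest Slug score of this list, 789, and Actg2 the highest Snail score, 1729. Luminal markers had Slug peaks in 14 of 23 cases (percentile 91.0) and Snail peaks in 15 (percentile 54.1). Kit, a receptor of luminal progenitor cells, had a Slug peak with a score of 1435 at chromosome 5, 75660198 to 75660918, and no Snail peak. Tbx3 and Cd14 had Snail scores of 1542 and 1323 and no Slug peak.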

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

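The alternatives were fixed before the data were examined, except the placement at gene ends and the 2 other ways of matching random lists, which were chosen after seeing the data. Neither list had peaks outside chromosomes 1 to 19, X and Y. A score of at least 100 left 16510 Slug and 17877 Snail peaks, so the Slug list was then the shorter one. As the score depends on depth, this cut may not be equally strict in the 2 lists. The overlap went from 12.1% to 10.1% of Slug peaks and from 16.6% to 9.01% of Snail peaks with that score, to 13.8% and 13.2% with equal numbers of peaks, to 3.73% and 5.47% with reciprocal overlap of 50%, and to 5.65% and 8.28% for midpoints within 100 bp. Its ratio to random placement went from 9.48 to 6.71 for Slug and from 8.86 to 3.44 for Snail when placement kept gene-end distances. The gene-end share of Snail peaks was 58.4% with a score of at least 100, 53.6% with a 2.5 kb window and 37.0% with protein-coding genes only; the Slug share was 18.7% and 6.25% under the last 2. Snail peaks had the higher share under each of these. The score difference between shared and other peaks was 155 for Slug and -71.1 for Snail with reciprocal overlap, and -10.4 for Slug within width quintiles; the cause was not tested. Genes with a Slug peak numbered 5428 with a score of at least 100, 2657 within 1 kb and 18208 within 50 kb, and genes with both 4030, 1943 and 15558. Slug lists above the random range went from 3 to between 2 (with a score of at least 100) and 6 (with gene bodies counted). For Snail they went from 7 to between 6 and 8. Of the percentiles of single lists and differences, 318 kept their side of the limits, 29 moved past one and 13 moved back inside, and none went from one extreme to the other. The calls of the epithelial factor list for Slug, and of the EMT factor, TGF-beta, Hippo, actin, cell cycle and apoptosis lists for Snail, held in all 6 alternatives. The polarity call for Snail ended within 1 kb (percentile 57.9) and with gene bodies (97.2). No paired analysis was possible because each group has 1 library. The motif, repeat and promoter CpG alternatives were not run, as no sequence was used here. With 1 library per factor and no read counts, the absence of a peak cannot be told from too little depth.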

Other observations

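The gene families, gene classes and chromosome values in this part, and the tests of peak width, of cell line or antibody and of housekeeping genes matched on length, were chosen after the results were seen. Replication-dependent histone genes had the highest shares of the 15 gene families examined within 1 kb of an end, in both lists. Of 63 such genes, 50 (79.4%) had a Slug peak within 1 kb, against 7.94% in random lists of like gene length, and 60 (95.2%) a Snail peak, against 27.0%. These genes lie in clusters and share peaks: the Slug calls rest on 43 distinct peaks, all 43 of which overlap a Snail peak, and the Snail calls on 39, of which 30 overlap a Slug peak. Keratin genes leaned the other way, with a Slug peak within 10 kb of 30 of 49 genes (61.2%, percentile 99.0) and a Snail peak near 17 (34.7%, percentile 0.005). Within 1 kb the Slug shares of keratin, solute carrier and Zfp genes were inside the random range, at percentiles of 81.9, 89.8 and 11.2. Solute carrier genes had Slug peaks near 218 of 347 (62.8%, against 52.7% in random lists, percentile 99.95) and Snail peaks near 230 (66.3%, percentile 2.85, or 0.05 within 1 kb). Zinc finger genes with Zfp symbols had Snail peaks near 345 of 397 (86.9%, against 71.0%) and Slug peaks near 154 (38.8%, against 51.4%). Serpin and protocadherin genes had few Snail peaks within 10 kb, at 15 of 63 and 11 of 69. Protocadherin genes were low for Slug too, at 22 of 69 (31.9%, against 47.8% in random lists, percentile 0.425). Within 1 kb their Slug share was inside the random range, at percentile 35.0. The Slug share of serpin genes within 10 kb was inside the range, at percentile 7.75.

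Transfer RNA genes also stood out in the Snail list. Of 408 such genes, 180 (44.1%, 39.4 to 49.0) had a Snail peak within 1 kb, against 2.30% for placed peaks, and 34 (8.33%, 6.02 to 11.4) a Slug peak, against 3.41%. The Snail calls rest on 133 distinct peaks, 96 of them over 1 kb from any end of a protein-coding gene. Olfactory receptor genes, which most cells keep silent, had a Snail peak within 10 kb in 37 of 1106 cases (3.35%, against 38.8%) and a Slug peak in 135 (12.2%, against 30.2%). Among chromosomes, 19 was the only one with more Snail than Slug peaks (1235 and 1101), and chromosome X had 2.07 Slug peaks for each Snail peak. The Y chromosome held 131 Slug and 19 Snail peaks.

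The crowding of Snail peaks at gene ends was weighed against 3 explanations. Wider peaks cannot be the whole cause: among peaks 300 to 400 bp wide the Snail share at gene ends was 19.8% and the Slug share 14.1%, a difference of 5.70 percentage points (3.79 to 7.62), although far below the difference over all peaks. Signal at the promoters of most active genes remains open as a candidate explanation. Of 164 housekeeping genes in families not looked at before, 91.5% had a Snail peak within 1 kb, against 48.9% of the 131 pooled EMT, epithelial, mesenchymal and matrix genes, a difference of 42.6 percentage points (32.6 to 51.7), and a share of at least 80% had been predicted before. That prediction was easily met, as ribosomal protein (95.8%), mitochondrial ribosomal (92.3%) and proteasome genes (92.5%) had like shares. Cell line and antibody cannot be told apart from the factor. By their labels, 0 of the 2 ChIP libraries map the other factor alone in the same cells. The antibody of the Snail library is labelled as directed at both proteins, so its peaks may include Slug sites in pBl.3G cells.

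The highest-scoring peaks of both lists were an exception to the low overlap. Of the top 100 Slug peaks by score 88 (80.2 to 93.0) overlapped a Snail peak, and 56 lay over 10 kb from any gene end. That distance was not particular to them: 56.2% of the top 1000 Slug peaks lay as far out. At a gene end lay 11% of the top 100, against 9.96% of all Slug peaks. Of the top 100 Snail peaks 71 (61.5 to 79.0) overlapped a Slug peak. Over 10 kb from any gene end lay 18% of these, against 4.9% of the top 1000 Snail peaks. Of the top 100 Slug peaks, 50 had a Snail partner and lay over 10 kb from any gene end. Their partners had a median Snail score of 1250. This was at percentile 99.1 of all Snail peaks that far from a gene end, whose median was 87.0. This is consistent with regions that collect reads in any library, such as collapsed repeats. Sites with a score of 3100 in both lists included the end of the ribosomal RNA pseudogene Rn18s-rs5. Others lay inside the protein-coding genes Mdga2 and Smo. Strong binding of both proteins at the same sites, or of Slug in both libraries, would give the same values. Without the input signal, which was not used here, neither can be told from regions that collect reads in any library.

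The frequency of Slug peaks near epithelial junction genes and epithelial factors was weighed against gene density and signal at most active genes. With random lists matched also on gene density, the percentiles were 100 and 99.99, which argues against gene density as the cause for either list. Housekeeping genes had a Slug peak within 10 kb in 51.2% of 164 cases, against 88.6% of the 44 epithelial genes, a difference of -37.4 percentage points (-47.4 to -22.7), and the epithelial share was at percentile 100 of housekeeping lists drawn to the same gene lengths (median 59.1%, from as few as 12 genes in a length quintile). The junction and factor lists were singled out for their high Slug shares, which neither the interval nor the percentile allows for. The epithelial polarity genes (68.8%) and luminal markers (60.9%) were left out. The junction and factor lists thus lay above the housekeeping level within 10 kb, but this does not decide on signal at most active genes. Housekeeping genes also had Slug peaks within 1 kb more often than random genes of like length (18.9% against 12.2%, percentile 99.4). A preference of Slug for epithelial genes, or open chromatin particular to this line, may each account for the pattern. No library of Slug alone in another cell line separates them.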
